A study of Homo sapiens with 6 samples.

How the data were processed

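RNA from 6 cultures of 76N cells was measured on 1-colour Affymetrix arrays, 1 array per culture. Per the labels, 3 cultures received a control siRNA and 3 an siRNA against Ecd, and the members of each group were biological replicates. The groups and replicate numbers were taken from the sample titles. The labels describe growth in DFCI-1 medium, siRNA transfection, Trizol extraction of total RNA and biotin labelling. The siRNA sequences, the siRNA dose and the time from transfection to harvest were not given in the sources used here.

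The authors deposited 1 intensity per probe set and array on a linear scale. These were MAS5 signals, per the submitters' processing notes, and the MAS5 version and scaling target were not given in the sources used here. The deposited table held 54675 probe sets on 6 arrays with 0 missing values, and it held no detection calls. The mean of the values between percentiles 2 and 98 was 499.94 on every array, so the arrays had already been brought to one level. That scaling sets the average of each array alike, so a change shared by all transcripts would not be seen. Signals were not rescaled further.

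Probe sets were named from the GEO platform annotation. Of the 54675 probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 were unnamed there and 62 were Affymetrix control probe sets. Gene identifiers of 41037 single-symbol probe sets matched the RefSeq gene table of GRCh38.p14, and 0 symbols needed an update. That table was otherwise used only to see which genes neighbour each other. Only single-symbol probe sets entered the gene tests, covering 19775 symbols. Genes without such a probe set were not analysed here. For each gene the probe set with the highest mean over the 6 arrays was used. Probe sets whose names end in _s_at or _x_at can bind transcripts of more than 1 gene, and they were allowed in the main analysis.

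Values were converted to log2(signal + 16). A fold change below is on this scale, which understates the change of dim transcripts. Genes were tested if their probe set lay in the upper 60% of all probe sets by mean, which corresponds to a signal of 84.6, leaving 14603 genes. Ecd siRNA was compared with control siRNA in limma 3.58.1 (lmFit, then eBayes with an intensity trend) under R 4.3.3, without covariates. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A gene is said to have risen or fallen only if it passed that threshold. The targeted transcript and the RNA quality probe sets were also compared by two-sided exact permutation tests, for which 3 against 3 arrays allow no p below 0.1.

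Gene lists were written from textbook knowledge. Each list was set against the other tested genes with limma's camera, with a preset correlation of 0.01 between genes, and adjusted over the 26 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way without reference to other genes, were run beside it. The named genes followed a rule. It took ECD, then the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 Ecd siRNA arrays lay wholly on 1 side of the 3 control arrays. It added up to 4 members per list with the smallest adjusted p among those past the threshold. For lists with fewer than 2 such members it took the 2 with the smallest p. TXNIP, RUVBL1, PRPF8, E2F1 and CDKN1A were always included. The grouping, tests, filter, pseudocount, lists, this rule and the alternative settings were chosen before the data were examined.

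The tests were tried on simulated data for the 14603 genes with 100 genes changed by 1 and 100 by 0.5 on the log2 scale, using the spread of the real arrays. Of these, 87% and 50% were recovered, 100% of the recovered genes had the right sign, and 8 of 145 calls were false. The simulated noise was independent between genes, and 200 of 14603 genes were changed. In the real data 3075 genes were called, so these shares need not hold there. The number of arrays limits the precision. The labels call the replicates biological, and p-values measure the spread between these 6 cultures. No scan dates were given in the sources used here, so scan batches were not checked. The alternatives tried were pseudocounts of 1 and 64, quantile normalization, a common median, no filter, a filter at the upper 40%, the mean of a gene's probe sets, preference for probe sets without _s or _x, every probe set on its own, eBayes without trend, array weights, the replicate number as a block, and each array left out in turn. The mean of a gene's probe sets took in all its single-symbol probe sets, also those under the filter.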

Results

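Transcript levels were measured in 76N cells, a line of normal human mammary epithelial cells, after transfection with a control siRNA (n = 3 arrays) or with an siRNA against Ecd (n = 3 arrays). Ecd is the protein of ECD, the human counterpart of the Drosophila gene ecdysoneless, annotated as a cell cycle regulator. The design has 1 comparison, which asks which transcripts differ between cells given the Ecd siRNA and cells given the control siRNA. Signals ran from 0.1 to between 24572.8 and 27986.8 per array, with medians of 128.7 to 147.6. Correlations of log2 signals across genes were 0.977 to 0.981 within a group and 0.952 to 0.961 between groups.

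The targeted transcript was lower in the cultures given Ecd siRNA. ECD, read by its only single-symbol probe set, had signals of 1076.6, 1011.4 and 1007.2 in the control arrays and 588.9, 599.8 and 542.5 in the Ecd siRNA arrays. The means were 1032 ± 38.9 and 577.1 ± 30.4 (SD, n = 3 each), so 55.9% of the control signal remained. The log2 change was -0.82 with an SE of 0.10 (limma adjusted p = 0.000172). In the exact permutation test p was 0.1, the smallest value that 3 against 3 arrays allow.

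Beyond the target, the transcripts of cell division fell the most and secreted proteases were among the largest rises. FOXM1, a transcription factor of G2/M genes, fell from a mean signal of 911.9 to 38.5, which lies under the filter signal of 84.6. MMP13, the collagenase 3 gene, rose 9.21-fold, from 429.7 ± 61.0 to 4070 ± 300.3 (SD, n = 3 each). Of 14603 genes tested, 3075 passed the threshold, 1468 of them higher and 1607 lower with Ecd siRNA. The larger changes were mostly falls, with 315 genes falling more than 2-fold against 180 rising as much, and 77 falling more than 4-fold against 14 rising. In 3050 of the 3075 the groups did not overlap, which was true of 36.4% of all tested genes against 10% by chance. The median log2 change of all tested genes was 0.008 and the median residual SD of a gene was 0.16.

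The 10 largest falls were those of FOXM1 (log2 change -4.12, SE 0.25), CSF3 (-3.77), TACC3 (-3.65), CEP55 (-3.57), BIRC5 (-3.36), CENPM (-3.35), FGFBP1 (-3.24), CDC45 (-3.18), NCAPH (-3.08) and NEK2 (-3.07). Apart from FOXM1, CSF3, which encodes the cytokine G-CSF, and FGFBP1, which encodes a carrier of fibroblast growth factors, these genes act in DNA replication or mitosis. BIRC5 encodes survivin, CEP55 acts in abscission and NCAPH is a condensin subunit. The 10 largest rises were those of MMP13 (3.20, SE 0.11), IL32 (2.98, SE 0.15), MMP10 (2.74), SYT12 (2.70), TNFAIP6 (2.69), ENO2 (2.62), BEND5 (2.58), EPHA4 (2.40), COXFA4L2 (2.34) and EPHA3 (2.20). IL32 is a cytokine gene, MMP10 encodes stromelysin 2, and EPHA3 and EPHA4 encode ephrin receptors. Cross-hybridisation between related metalloprotease transcripts was not excluded for MMP10 and MMP13. All 20 passed the limma threshold, with adjusted p = 8.09e-08 for MMP13 and 1.93e-06 for FOXM1. The sizes of the falls to dim signals depend on the pseudocount, and FOXM1, read by an _x_at probe set, was at -4.61 with a pseudocount of 1 and at -3.25 with 64. Other probe sets gave smaller values for BIRC5 (-0.73 in probe sets without _s or _x), and SYT12 (0.82) and EPHA3 (1.02) were lower as the mean of all their probe sets, and 1 of the 2 probe sets of SYT12 above the filter went the other way. The 2 probe sets of EPHA3 above the filter were higher.

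**Figure D1:**
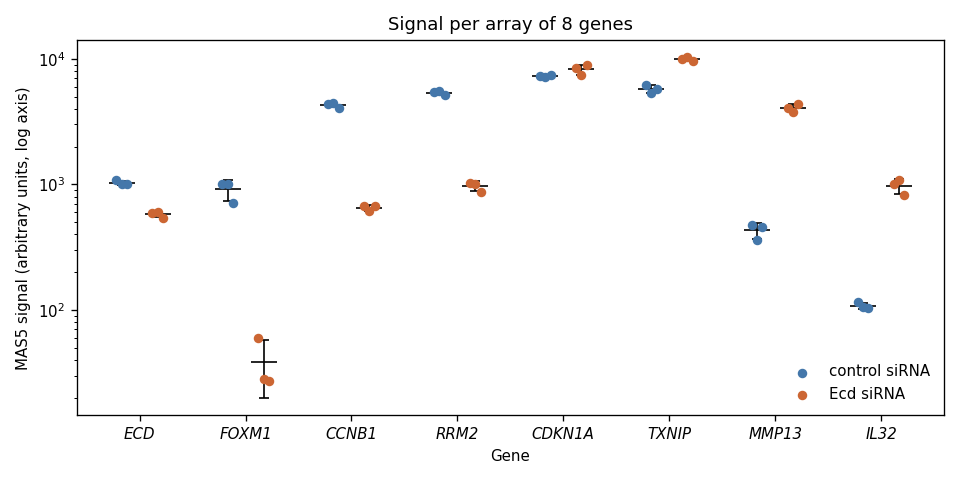
MAS5 signals (arbitrary units, log axis) of 8 genes in each control siRNA array (blue) and each Ecd siRNA array (orange), with horizontal lines for means and bars for SD, n = 3 per group. ECD fell to 55.9% of the control mean, FOXM1, CCNB1 and RRM2 fell further, MMP13, IL32 and TXNIP rose, and CDKN1A did not pass the threshold.

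**Figure D2:**
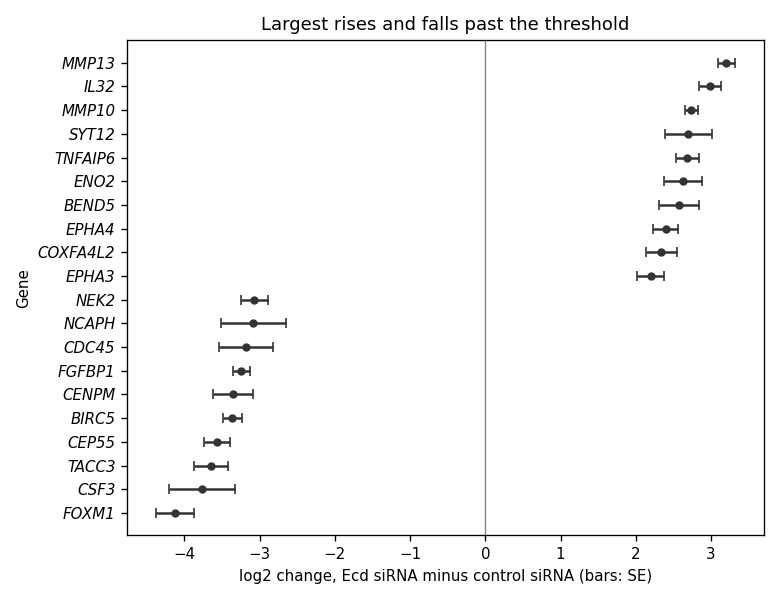
Log2 changes, Ecd siRNA minus control siRNA, of the 10 largest rises and the 10 largest falls among genes past the threshold with non-overlapping groups, with bars for the standard error (n = 3 arrays per group). Values run from -4.12 for FOXM1 to 3.20 for MMP13.

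Genes of mitosis and DNA replication fell as groups. All 40 tested G2/M and mitosis genes fell, with a median log2 change of -2.41 and a range of -4.12 to -0.77. Cyclin B1 (CCNB1) dropped from 4292 to a signal of 652.8, a log2 change of -2.69 (adjusted p = 7.17e-08). ANLN, a cytokinesis scaffold, fell by 2.79 on the log2 scale, HMMR, a spindle protein gene, fell by 3.03, and TOP2A, the topoisomerase II alpha gene, fell by 2.74. The same 40 genes fell when adjusted over the list alone, and the list lay lower than the other tested genes (camera adjusted p = 5.2e-50, and adjusted p = 0.0317 with an estimated correlation).

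In the list of G1/S and DNA replication genes, 37 of 39 tested members fell and 0 rose, with a median of -1.36, and 38 fell when adjusted over the list alone. RRM2, a ribonucleotide reductase subunit gene, changed by -2.46, GINS1, part of the replicative helicase, by -2.17, UHRF1, which acts in maintenance of DNA methylation, by -2.10, and TYMS, the thymidylate synthase gene, by -1.40. The 2 members not past the threshold were E2F2 (-1.03, adjusted p = 0.0924) and GINS3 (-0.32, adjusted p = 0.257). E2F1 was at -0.92 with an adjusted p of 0.0396. That call was lost on leaving out control replicate 1, 2 or 3 or Ecd siRNA replicate 1 or 3, with adjusted p up to 0.131. It was also lost without the filter (0.0764), without the intensity trend (0.0642) and with the mean of probe sets (0.061). The list lay below the other tested genes (camera adjusted p = 1.09e-31, and adjusted p = 0.014 with an estimated correlation). Members that are named here and below only to complete a count of 5 or fewer, such as E2F2, were chosen after their values were seen.

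Homologous recombination and Fanconi genes moved the same way, with 19 of 25 tested members falling, 0 rising and 6 not past the threshold. The median was -0.76, and 20 fell when adjusted over the list alone. Among these falls were those of the recombination gene MND1 (-2.13), of FANCI (-1.88) and of UBE2T (-1.63), a ubiquitin-conjugating enzyme gene of the Fanconi pathway. Camera gave an adjusted p of 2.89e-13 for this list, and adjusted p = 0.014 with an estimated correlation. These 3 cell cycle and repair lists were the only ones of the 26 that passed with an estimated correlation, and 16 passed with the preset one.

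Several groups of biosynthetic genes were lower after Ecd siRNA. Ribosome biogenesis genes fell in 20 of 30 tested members with 0 rises and 10 not past the threshold, and the median was -0.39, with 24 falls when adjusted over the list alone. LYAR, a nucleolar protein gene, changed by -0.81, the small nucleolar RNP gene NOP58 by -0.66, the fibrillarin gene FBL by -0.61 and UTP4, a small-subunit processing gene, by -0.56. Camera gave adjusted p = 1.12e-10 for the list, but adjusted p = 0.0839 with an estimated correlation. Sterol synthesis genes fell in 10 of 18 tested members with 0 rises and 8 not past the threshold, with a median of -0.51, and 10 fell when adjusted over the list alone. ACAT2, the cytosolic thiolase that feeds the mevalonate pathway, dropped from 1834 to 381.1 (log2 change -2.23), HMGCS1 changed by -1.07 and FDPS, the farnesyl diphosphate synthase gene, by -0.82. This list had a camera adjusted p of 2.24e-07, and adjusted p = 0.0839 with an estimated correlation.

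Spliceosome genes fell in 14 of 39 tested members, with 0 rises, 25 not past the threshold and a median of -0.20, and 16 fell when adjusted over the list alone. Those that fell included the Sm protein genes SNRPF (-0.76), SNRPB (-0.57) and SNRPD1 (-0.55, or -0.96 in probe sets without _s or _x). SNRPE was at -0.39 in its brightest probe set but at 0.18 as the mean of its probe sets (adjusted p = 0.255), and it did not pass in probe sets without _s or _x (adjusted p = 0.138). Its 2 probe sets above the filter were lower. PRPF8, whose protein is the core U5 factor, was at -0.17 and did not pass the threshold (adjusted p = 0.103). The camera adjusted p was 6.6e-06, and adjusted p = 0.179 with an estimated correlation. Among mRNA export genes, 6 of 20 fell, 0 rose and 14 did not pass, with a median of -0.24 and 8 falls when adjusted over the list alone. The RNA helicase gene DDX39A was at -1.81 (adjusted p = 1.25e-06), the adaptor gene ALYREF at -1.13, the nucleoporin gene NUP98 at -0.92 (-0.47 as the mean of its probe sets) and NXT1 at -0.40. For this list camera gave adjusted p = 0.000778, and adjusted p = 0.0897 with an estimated correlation.

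Genes of the R2TP complex, HSP90 co-chaperones and PIKK kinase assembly fell in 7 of 21 tested members, with 0 rises, 14 not past the threshold and a median of -0.08, and 9 fell when adjusted over the list alone. RUVBL1, an ATPase of R2TP, was at -0.58 (adjusted p = 0.00684) and TTI1, a partner of PIKK kinases, at -0.68. The call for PRKDC, the DNA-PK catalytic subunit gene (-0.38, adjusted p = 0.01), was lost without the intensity trend (0.0552) and as the mean of its probe sets (-0.14, adjusted p = 0.596). The 2 probe sets of PRKDC above the filter were lower. The list had a camera adjusted p of 0.0174, and adjusted p = 0.116 with an estimated correlation. Its median was -0.14 without control replicate 3, -0.13 without Ecd siRNA replicate 1, -0.16 with the mean of probe sets and -0.20 with probe sets without _s or _x. Oxidative phosphorylation genes fell in 9 of 30 tested members, with 0 rises, 21 not past the threshold, a median of -0.09 and 11 falls when adjusted over the list alone. Examples were SDHA of complex II (-0.92, read by an _x_at probe set), the ATP synthase gene ATP5MC1 (-0.69) and NDUFV2 of complex I (-0.33). The list's adjusted p was 0.0154, and adjusted p = 0.422 with an estimated correlation. It was 0.061 without control replicate 2, 0.0801 without Ecd siRNA replicate 2 and 0.119 with the mean of probe sets, and the median was -0.06 without Ecd siRNA replicate 3 and -0.18 with probe sets without _s or _x.

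PERK-ATF4 integrated stress response genes lay lower as a list although its members went both ways. Of 34 tested, 3 rose, 11 fell and 20 did not pass the threshold, and the median was -0.13. Adjusted over the list alone, 5 rose and 12 fell. The cystine transporter gene SLC7A11 changed by -1.84, from 2098 ± 290.6 to 577.4 ± 112 (SD, n = 3 each), and the mitochondrial folate enzyme gene MTHFD2 by -0.50. The 3 that rose were VLDLR (0.86), PSPH (0.39) and CEBPB (0.24). Camera gave adjusted p = 0.0103, and adjusted p = 0.284 with an estimated correlation.

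Among the groups that lay higher after Ecd siRNA were genes of glucose handling. Of 22 tested glycolysis genes, 6 rose, 1 fell and 15 did not pass the threshold, with the same counts of 6 and 1 adjusted over the list alone. The list's mean of 0.36 was well above its median of 0.13. Among the rises were those of the neuronal enolase gene ENO2 (2.62), the regulatory enzyme gene PFKFB4 (1.99, adjusted p = 6.7e-07), PFKFB3 (0.85) and the glucose transporter gene SLC2A1 (0.81). LDHB was the 1 that fell (-0.22). The camera adjusted p was 0.000306, and adjusted p = 0.116 with an estimated correlation. Of the 4 glucose-responsive arrestin genes, TXNIP, the thioredoxin-interacting protein gene, rose from 5745 ± 398.1 to 9986 ± 301.1 (SD, n = 3 each; log2 change 0.80, limma adjusted p = 1.85e-05). ARRDC4 (1.29) and ARRDC3 (1.02) rose too, 3 rose when adjusted over the list alone, and ARRDC2 was at 0.32 (adjusted p = 0.364). This list had a median of 0.91 and a camera adjusted p of 0.000306, and adjusted p = 0.117 with an estimated correlation.

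Autophagy and lysosome genes rose in 12 of 35 tested members, fell in 3 and did not pass the threshold in 20, with a median of 0.20. Adjusted over the list alone, 14 rose and 3 fell. The ATG8 family genes GABARAPL1 (0.79), GABARAP (0.65) and MAP1LC3B (0.58) rose, as did the lysosomal protease gene CTSD (0.81), and the 3 that fell were ATG3 (-0.44), GLA (-0.37) and CTSL (-0.35). For this list camera gave adjusted p = 0.00156, and adjusted p = 0.0897 with an estimated correlation.

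Markers of fibroblasts, another cell type of the breast, also lay higher. Of 14 tested members, 8 rose, 0 fell and 6 did not pass the threshold, with a median of 0.59 and 8 rises when adjusted over the list alone. LOX, a collagen cross-linking enzyme gene, rose from 1928 ± 153.1 to 5043 ± 515.6 and the membrane protease gene FAP from 2610 to 5334 in mean signal. MMP2 (0.79) and COL6A1 (0.91) lost their calls as the mean of their probe sets, at 0.20 (adjusted p = 0.425) and 0.60 (adjusted p = 0.144), COL6A1 also in probe sets without _s or _x (adjusted p = 0.693), and 1 of the 2 probe sets of MMP2 went the other way. The 4 probe sets of COL6A1 above the filter were all higher. Of the 21 markers written, these 14 were above the filter and 0 were on another list, and without the filter the list's median was 0.18. Camera gave adjusted p = 0.000111, and adjusted p = 0.0738 with an estimated correlation.

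Basal and myoepithelial markers lay higher beside the fibroblast markers (median of the latter 0.59). Of 18 tested, 8 rose, 0 fell and 10 did not pass the threshold, with a median of 0.25 and 8 rises when adjusted over the list alone. The membrane metallopeptidase gene MME (1.18), the actin-binding protein gene TAGLN (1.09), the myosin kinase gene MYLK (0.70) and the matrix protein gene SPARC (0.47, or 0.76 in probe sets without _s or _x) rose. TAGLN, which is also on the YAP and TGF-beta list, was at 0.51 in probe sets without _s or _x (adjusted p = 0.184). The camera adjusted p was 0.00112, and adjusted p = 0.0897 with an estimated correlation. With the mean of each gene's probe sets it was 0.0565, at a median of 0.13. The median was 0.15 without control replicate 3 and 0.17 without Ecd siRNA replicate 2. Squamous differentiation genes went both ways, with 9 of 29 rising, 4 falling and 16 not past the threshold, a median of 0.17, and 10 rises and 5 falls when adjusted over the list alone. The stress keratin gene KRT16 (1.14), the kallikrein gene KLK7 (0.96) and the protease inhibitor gene SLPI (0.64) rose. SLPI is also on the list of luminal epithelial markers. The 4 that fell were TGM3 (-1.40), SPRR2B (-1.20), KLK10 (-0.80) and KLK5 (-0.24). This list had a camera adjusted p of 0.0154, and adjusted p = 0.263 with an estimated correlation.

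**Figure D3:**
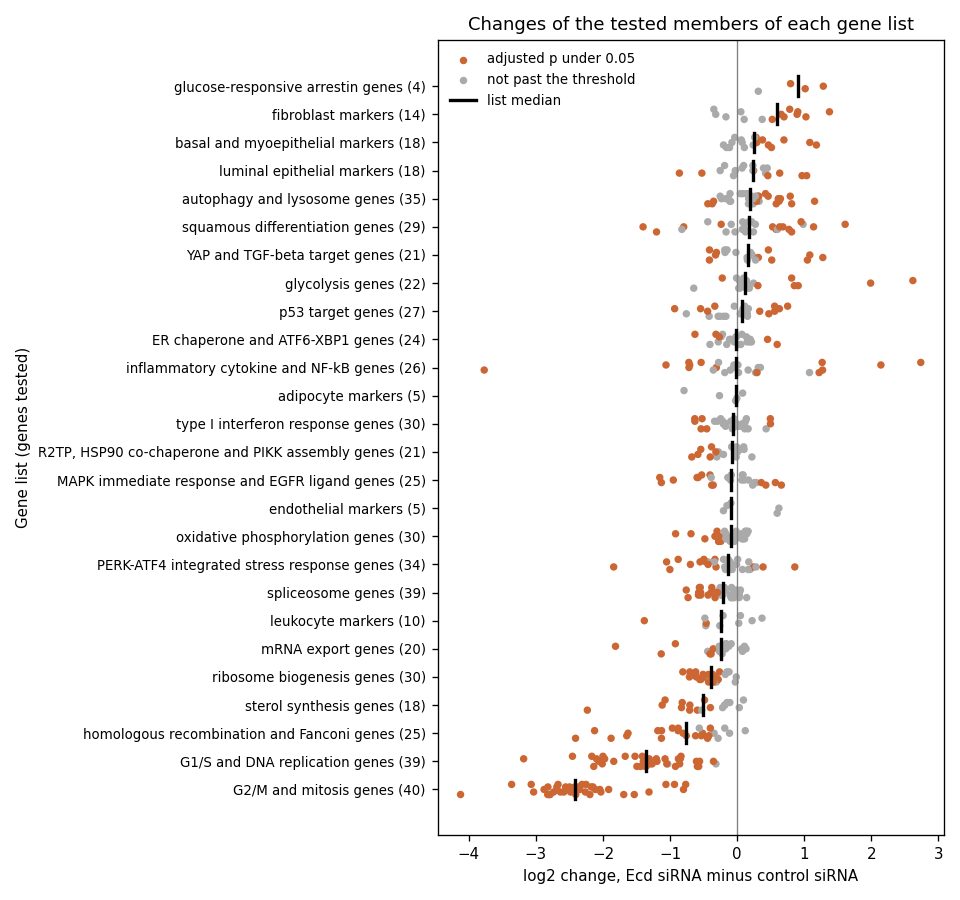
Log2 changes, Ecd siRNA minus control siRNA, of each tested member of the 26 gene lists, with orange points for genes past the threshold, grey points for the others, and a black bar for each list's median. List medians run from -2.41 for G2/M and mitosis genes to 0.91 for the glucose-responsive arrestin genes.

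The other 10 lists did not pass camera's threshold, although most held genes that moved in both directions. Of 27 tested p53 target genes, 6 rose, 4 fell and 17 did not pass, with a median of 0.08, a mean of 0.002 and an adjusted p of 0.558. The median was 0.048 without control replicate 3 and 0.043 without Ecd siRNA replicate 1. Adjusted over the list alone, 6 rose and 8 fell. CYFIP2 (0.75), TP53I3 (0.56) and SUSD6 (0.56) rose, and the 4 that fell were GDF15 (-0.93), POLH (-0.54), PMAIP1 (-0.44) and TRIAP1 (-0.33). CDKN1A, the p21 gene, had signals of 7298 ± 105.2 and 8227 ± 770.6 (SD, n = 3 each), a log2 change of 0.17 that did not pass the threshold (limma adjusted p = 0.149). Without Ecd siRNA replicate 2 it was at 0.25 and passed (adjusted p = 0.0392). Inflammatory cytokine and NF-kB genes split into 6 rises, 7 falls and 13 not past the threshold among 26 tested, or 7 and 7 adjusted over the list alone (adjusted p = 0.919). MMP10 (2.74), MMP1 (2.15) and PTGS2 (1.22), the cyclooxygenase 2 gene, rose, while IL1B (-1.06) and CSF3 (-3.77) fell. The median of this list was -0.017 while its mean was 0.09 and camera pointed upwards.

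YAP and TGF-beta target genes held 6 rises, 4 falls and 11 not past the threshold among 21, or 9 and 5 adjusted over the list alone, with a median of 0.16, beside the rise of the fibroblast markers (median 0.59). The cell cycle inhibitor gene CDKN2B (1.28), which encodes p15, and CCN2 (1.05), a matrix-associated growth factor gene, rose, and the 4 that fell were AJUBA (-0.41), CCN1 (-0.41), COL4A1 (-0.32) and AXL (-0.31). The list's adjusted p was 0.0533, and adjusted p = 0.284 with an estimated correlation. It passed without control replicate 3 (0.0313), without Ecd siRNA replicate 2 (0.0388) and with array weights (0.0484). MAPK immediate response and EGFR ligand genes held 4 rises, 9 falls and 12 not past the threshold among 25, or 7 and 10 adjusted over the list alone, with a median of -0.09 and an adjusted p of 0.23. The median was -0.045 without control replicate 3, -0.005 without Ecd siRNA replicate 1 and -0.17 without Ecd siRNA replicate 3. FOSL1, an AP-1 subunit gene, fell by 1.13, and the ligand genes EREG and TGFA fell by 0.95 and by 0.53. The 4 that rose were FOS (0.66), DUSP1 (0.57), JUN (0.43) and SPRY1 (0.36), and DUSP1, with 2 of its 3 probe sets higher, lost its call as their mean (0.37, adjusted p = 0.172). Type I interferon response genes held 2 rises and 5 falls among 30, with 23 not past the threshold, the same counts adjusted over the list alone, a median of -0.07 (-0.13 without Ecd siRNA replicate 1 and -0.04 without Ecd siRNA replicate 2) and an adjusted p of 0.23. CXCL10 (0.50) and ISG15 (0.50) rose, and the 5 that fell were IFIT2 (-0.63), IFIT3 (-0.63), OASL (-0.54), OAS3 (-0.52) and IFIT5 (-0.45), of which OASL was lost in probe sets without _s or _x (adjusted p = 0.298) and IFIT2 as the mean of its probe sets (adjusted p = 0.0535). The 2 probe sets of IFIT2 above the filter were lower. In the ER chaperone and ATF6-XBP1 list, OS9 (0.60) and DNAJB9 (0.46) rose, SDF2L1 (-0.63), MANF (-0.32) and XBP1 (-0.27) fell and 19 of 24 did not pass, with the same counts adjusted over the list alone and an adjusted p of 0.919. Its median was -0.014 and its mean -0.021 while camera pointed upwards. The call for MANF was lost without control replicate 2 (0.0622), control replicate 3 (0.0636), Ecd siRNA replicate 2 (0.0729) or Ecd siRNA replicate 3 (0.0587), and without the intensity trend (0.0852).

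Luminal epithelial markers held 5 rises, 2 falls and 11 not past the threshold among 18, or 6 and 2 adjusted over the list alone, with a median of 0.24 and an adjusted p of 0.189. The median was 0.15 without control replicate 1, 0.10 without control replicate 3 and 0.09 without Ecd siRNA replicate 2. PROM1 (1.04), AGR2 (0.97), SLPI (0.64), GATA3 (0.46) and CD24 (0.25) rose, and ALDH1A3 (-0.86) and KRT18 (-0.53) fell. The call for GATA3 was lost in probe sets without _s or _x (adjusted p = 0.218) and that for ALDH1A3 as the mean of its probe sets (adjusted p = 0.106). ALDH1A3 had only 1 probe set above the filter, so that mean adds probe sets under it. Of 10 tested leukocyte markers, 0 rose, 8 did not pass the threshold and 2 fell, also when adjusted over the list alone (median -0.23, adjusted p = 0.246). Leaving out control replicate 1 or 2 or Ecd siRNA replicate 1 or 3 brought this median to between -0.15 and -0.10, and the filter at the upper 40% to 0.025. The genes that fell were CORO1A (-1.38) and LAPTM5 (-0.46, adjusted p = 0.0364), and the call for LAPTM5 was lost on leaving out any array except Ecd siRNA replicate 2, with adjusted p up to 0.113, without the filter (0.0659) and without the intensity trend (0.0549), while the mean of its probe sets was at -0.88 (adjusted p = 0.00207). None of the 5 tested adipocyte markers (median -0.022, adjusted p = 0.56) or the 5 tested endothelial markers (median -0.09, mean 0.16, camera upwards, adjusted p = 0.915) passed, also when adjusted over the list alone. With 1 array left out the adipocyte median ran from -0.122 without Ecd siRNA replicate 2 to 0.048 without Ecd siRNA replicate 1. The adipocyte members with the smallest p were PPARG (-0.79, adjusted p = 0.0772) and LIPE (-0.26, adjusted p = 0.426). PPARG passed without Ecd siRNA replicate 3 (0.0344) and LIPE as the mean of its probe sets (-0.77, adjusted p = 0.0252). LIPE was at -0.12 without Ecd siRNA replicate 1 and at -0.40 without Ecd siRNA replicate 2. The endothelial ones were CLDN5 (0.60, adjusted p = 0.152) and PLVAP (0.62, adjusted p = 0.246).

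Probe sets that report on RNA quality and labelling gave no exact p below 0.3, in a test that cannot go below 0.1. The log2 ratio of the 3 prime to the 5 prime control probe set was -0.034 ± 0.005 in control and -0.016 ± 0.021 in Ecd siRNA arrays for GAPDH (SD, n = 3 each, exact permutation p = 0.4). For ACTB it was 0.13 ± 0.03 and 0.17 ± 0.06 (exact permutation p = 0.5). The spike-in probe sets bioB, bioC, bioD and cre differed by -0.28, -0.11, -0.04 and -0.20 on the log2 scale (exact permutation p = 0.3, 0.6, 0.8 and 0.3). The labels give 1 Ecd siRNA condition, so effects of this siRNA on other transcripts cannot be separated from those of lower ECD. Without detection calls, a low signal was not taken as absence of a transcript.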

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

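All settings below were planned. ECD stayed lower and past the threshold under every setting run, with log2 changes of -0.85 to -0.77. The count of 3075 genes became 2250 without the intensity trend, 2319 with the mean of probe sets and 3301 with array weights, and stayed within 1.5 times under every setting. A common median gave 50.5% higher genes against 47.7%. The alternative scalings left the median of all genes at or below 0.023. Of the 3075 calls, 2785 were shared under the common median and 3014 under quantile normalization, with 0 of opposite sign, and 2 of the 2549 shared calls had opposite signs with probe sets without _s or _x. Testing every probe set on its own (27009 probe sets) gave 2243 higher against 1468 genes, since a gene then counts once per probe set. Leaving out each array in turn gave 2206 to 2784 genes, 1043 to 1329 of them higher and 1163 to 1517 lower, and 15 to 17 lists, with fewer arrays in each fit.

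Camera with an estimated correlation passed 3 lists against 16. A higher correlation between members cannot account for all of these losses. The fibroblast list had an estimated correlation of -0.016, below the preset 0.01, yet its camera p before adjustment went from 3e-05 to 0.0114. For the autophagy and lysosome list, estimated at 0.0096, that p went from 0.000722 to 0.0273. The versions also differ in the degrees of freedom from which p is taken. With an estimated correlation these are the residual ones, set by the small number of arrays. With a preset correlation they are set by the number of genes. Fewer degrees of freedom give a larger p for the same statistic. A list lost with an estimated correlation therefore need not have correlated members. The share of the losses due to each was not tested. Fry passed 22. The remaining settings passed 14 to 17. Among lists, a direction was reversed only in 3 that passed under none of these settings with camera, where camera's direction changed. For ER chaperone and ATF6-XBP1 genes this happened under quantile normalization (median -0.04), with probe sets without _s or _x (-0.009) and without the intensity trend (-0.014), and the medians with 1 array left out ran from -0.037 to 0.007. For endothelial markers it happened with the filter at the upper 40% (-0.15), and with arrays left out the medians ran from -0.171 to 0.062. For inflammatory cytokine and NF-kB genes that range was -0.049 to -0.013. SNRPE was the 1 named gene that reversed, to 0.18 with the mean of probe sets. Its 2 probe sets above the filter were lower, so the reversal came from probe sets under the filter, which that mean includes. Over all named genes and settings, 1913 comparisons kept direction and call, 38 lost the call and 3 gained it.

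Control and Ecd siRNA arrays share replicate numbers. The plan, fixed before the data were examined, did not take the numbers to pair the arrays. Deviations of same-numbered arrays correlated at -0.01, 0.08 and 0.15 (other pairs -0.13 to 0.06), and 2 of 3 control arrays correlated best with their own number. Pairing is therefore not excluded. With the replicate number as a block, 3277 genes passed (1582 higher, 1695 lower), 17 lists passed and ECD was at -0.82. The YAP and TGF-beta list passed (adjusted p = 0.0435), as with array weights (0.0484), and the block changed no other list or named gene call. Genes near the filter signal of 84.6 have the least certain folds, and a dim transcript could not be told from an absent one.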

Other observations

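The tests of RNA degradation, of cross-hybridisation, of the 4 further metalloproteases of the cluster and of the histone set without H2AC8 were chosen only after their values were seen, and the other tests were written down before theirs, although each was prompted by the same data. The genes in the next paragraph were chosen after their values were seen.

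Some further regulators of the cell cycle fell and others did not pass the threshold. RBL1, the p107 gene, fell from 497.3 to 145.1 (log2 change -1.68, limma adjusted p = 7.63e-05), and E2F7 (-1.01) and CDK2 (-0.90) fell as well. CCND3 was at -0.49, CDK4 at -0.41 and CCND1 at -0.38, all past the threshold. RB1 (-0.25, adjusted p = 0.0972), RBL2 (0.02), CDKN1B (0.06), CDKN2A (0.19, adjusted p = 0.162) and MYC (0.07) did not pass the threshold. LMNB1, the lamin B1 gene, was at -2.74 and HMGB2, a chromatin protein gene, at -2.05. Among 4539 probe sets without a gene name above the filter, 173 passed, 82 higher and 91 lower.

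The fall of G2/M and DNA replication genes was set against technical explanations. The authors' scaling of the arrays is argued against for the fall relative to other genes. The G2/M median was still -2.40 under the alternative scaling with the smaller fall, and the median of all tested genes under the main setting was 0.008. The alternative scalings also bring the arrays to one level, so they cannot test a change shared by all transcripts. Degradation of RNA in the Ecd siRNA samples is argued against by 3 prime to 5 prime ratios that differed by at most 0.037 between groups. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 3075 genes and the highest other split gave 0, but 10 splits are too few for a share under 0.05. Effects of the siRNA on transcripts other than ECD, differing culture density and an effect of lower ECD itself remain open and untested.

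The rise of the fibroblast marker list could come from fibroblasts in the Ecd siRNA cultures, which would bring their abundant transcripts. Only 1 of 5 of these rose, COL1A1 (0.53). COL1A2 went from a mean signal of 371.6 to 340.6 and DCN from 209.5 to 232.3, neither past the threshold. COL3A1 (55.2 and 23) and LUM (71.4 and 83.3) stayed under the filter signal and were therefore not tested, while FAP went from 2610 to 5334. These signal levels, more than the count of rises, argue against added fibroblasts as the source. A change within the epithelial cells stays open and was not tested further.

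MMP1, MMP7, MMP10 and MMP13 rose together, the smallest rise being 2.09, for MMP7. All 4 are read by probe sets named _at without _s or _x, so a comparison by probe set type decides nothing and cross-hybridisation among related metalloproteases stays open. In the RefSeq table the 9 protein-coding genes from MMP7 to MMP13 are all metalloproteases, so a change particular to this cluster was tested. The 8 tested cluster members had a mean log2 change of 1.45, with 5 past the threshold, against 0.17 for 8 metalloproteases elsewhere, with 3 past it, a difference of 1.28 (permutation p = 0.0287, and 0.0287 adjusted over the 3 hypothesis tests). The 4 cluster members that had not prompted the test differed by only 0.19 (permutation p = 0.653). Whether the cluster or its 4 members alone account for the rise cannot be told apart, because the genes that gave the idea carry the difference.

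ENO2, PFKFB4 and COXFA4L2, which hypoxia is known to induce, were among the large rises, and a wider hypoxia-type response may be present. In a list of 25 hypoxia target genes outside the glycolysis list, 20 of 23 tested members rose and 0 fell, with a median log2 change of 0.58. Camera of limma gave an adjusted p = 2.13e-15 over the 3 hypothesis tests, from 7.11e-16 before adjustment, and unadjusted p = 0.000974 with an estimated correlation. Adjusted over the list alone, 20 rose. MXI1 (0.75), BNIP3L (0.66) and FAM162A (0.87) are examples. Medians ran from 0.45 to 0.62 over 17 other settings. VEGFA (0.08), ERO1A (0.12) and ANGPTL4 (-0.02) did not pass, nor did the glycolytic LDHA (0.03), PGK1 (0.12) and PDK1 (0.02), which hypoxia also induces. Oxygen, density and medium use of the cultures were not given in the sources used here, so a culture effect and an effect of lower ECD remain open.

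The histone gene H2AC8 rose (1.56) while DNA replication genes fell, so a wider rise of replication-dependent histone transcripts was tested. Of 19 tested histone genes, 10 rose and 0 fell, also when adjusted over the list alone, with a median of 0.58. Camera of limma gave an adjusted p = 6.29e-06 over the 3 hypothesis tests, from 4.19e-06 before adjustment. With an estimated correlation p was 0.0583, and 4 of 17 other settings gave such a p under 0.05. Without H2AC8, which prompted the test, 9 of 18 rose, with a median of 0.57, and p was 0.0765 with an estimated correlation. The median of the 19 ran from 0.25 without the filter to 0.83 with the filter at the upper 40%. Examples are H2AC6 (1.19), H2BC5 (1.18) and H1-2 (1.07). The probe sets of these near-identical genes may share signal, so the 19 are not independent, and whether many genes rose or a few cannot be told apart here. These RNAs normally lack poly(A) tails, and a rise in polyadenylated forms could raise such a signal without more histone mRNA, which was not tested.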
